A study of Rattus norvegicus with 36 samples.

How the data were processed

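The analysis started from the count of reads per gene that the authors deposited for 36 libraries. Per the submitters' processing notes, reads were trimmed with fastp, aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. Genome build, annotation release and strand setting are not given in the sources used here. A transcript and an antisense or overlapping neighbour therefore cannot be told apart, and reads of near-identical copies of a gene may be shared or lost, which holds for Mif with its 9 listed copies. The table held 32521 genes, of which 9991 had no count in any library, and 500 gene names were held by more than 1 entry. Columns were assigned to groups by their names. The columns carry rat numbers while the labels number samples 1 to 6 in each group, so the planned replicate block was not fitted. Among the 36 libraries 0 pairs were identical.

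Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 14154, and scaled by TMM. One quasi-likelihood fit of all 36 libraries used the means of the 6 groups, and contrasts of these means gave the plasma effect at each time, its differences between times and the changes over time in controls. Adjusted p-values are Benjamini-Hochberg values of edgeR for single genes, with a threshold of 0.05. Log2 fold changes are treated over control or later over earlier, and standard errors are the log2 fold change divided by the root of the test statistic. CPM values use TMM-scaled library sizes. Against a group without any count the fold is a lower bound set from 3 counts, and with 1 to 3 counts a ratio with a counting interval is given.

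Before the data were examined, 41 gene lists for immune, stress, vessel, matrix, muscle fibre, energy and other tissue markers were fixed together with a panel of 35 genes. Of 780 symbols 736 were matched by name, 14 by an older symbol and 30 not at all. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. List p-values are adjusted over the 41 lists. Counts given over the list alone use adjusted p-values over its members only. Genes were named by a fixed rule. In each plasma contrast these are up to 6 largest rises and 6 largest falls among genes past the threshold with average log2 CPM above 1, up to 3 members of a list with called members, and the panel. In the other contrasts they are 5 rises, 5 falls and the panel. Some genes that the rule selects are not reported here.

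Fixed alternatives were other scalings (RLE, upper quartile, library size only), no filter or a stricter one, DESeq2 1.42.0, voom with sample quality weights, robust fitting, a threshold of 0.01, a minimum log2 fold change of 1, a fit of the 12 libraries of each contrast and the omission of each library in turn. Alternatives chosen after the data were seen were a term for the rat-number series, each series alone, the omission of 3 libraries standing apart, the omission of control rats 139 and 140, 2 surrogate variables of sva 3.50.0, and the time contrasts in treated rats. Counts of genes and of lists, correlations between times and the difference between the rat-number series were also compared with 100 groupings of the same rats, the real one included. At the preset correlation, groupings other than the real one called up to 22 lists at 6 hours, 25 at day 4 and 19 at day 14. Small adjusted p-values of lists therefore do not by themselves set a shift apart from chance. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

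To measure what the tests could find, counts were simulated from the mean of each gene at each time and its dispersion. In each plasma contrast 100 genes were changed per fold, all picked among genes averaging above 1 CPM. Recovery below that level was not measured, and the adjusted threshold is harder to pass where fewer genes change. Each gene was drawn independently, so the simulation lacks the libraries standing apart and the difference between the rat-number series. Recovery in the real data may therefore be lower. At 6 hours edgeR recovered 37 of 100 genes at 2-fold and 87 at 4-fold, at day 4 53 and 88, and at day 14 51 and 91. DESeq2 recovered 53 and 90, 60 and 95, and 58 and 94, and voom 42 and 86, 47 and 88, and 45 and 84. Total counts were 4.61 to 20.09 M, and only 1 library lay below 9.49 M. The biological coefficient of variation was 0.404. All columns of values in the table were used. Histology and protein levels were not analysed here.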

Results

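The data are RNA-seq counts from the biceps femoris muscle of Sprague-Dawley rats, taken from surgical incisions that were treated with cold plasma or left untreated as controls. Tissue was collected at 6 hours, day 4 and day 14, with 6 rats in each of the 6 groups, 36 libraries in all. Rats sampled at 6 hours had 1 operation, on the day of treatment. Rats sampled at day 4 and day 14 had a first operation a week before the revision surgery, so time and number of operations change together. Total counts ran from 4.61 to 20.09 M counts per library, with a median of 16.49 M, and 14636 to 17426 genes were detected per library. Control libraries at 6 hours held 4.61 to 18.37 M counts and treated ones 13.31 to 17.72. The other ranges were 12.36 to 19.12 (control, day 4), 13.33 to 20.09 (treated, day 4), 13.8 to 18.84 (control, day 14) and 12.32 to 19.11 M (treated, day 14).

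Of 32521 genes, 14154 passed the expression filter. The biological coefficient of variation was 0.404. In 3 control libraries the median correlation with the rest of the group was below 0.9: rat 139 (0.87) and rat 140 (0.875) at 6 hours, and rat 177 (0.868) at day 14. Their mitochondrially encoded transcripts took 38.3%, 36.9% and 29.1% of all counts. Rats carry numbers in 2 series, 14 to 67 (15 libraries) and 126 to 195 (21 libraries). All 12 libraries of the 6-hour groups are in the high series.

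**Figure D1:**
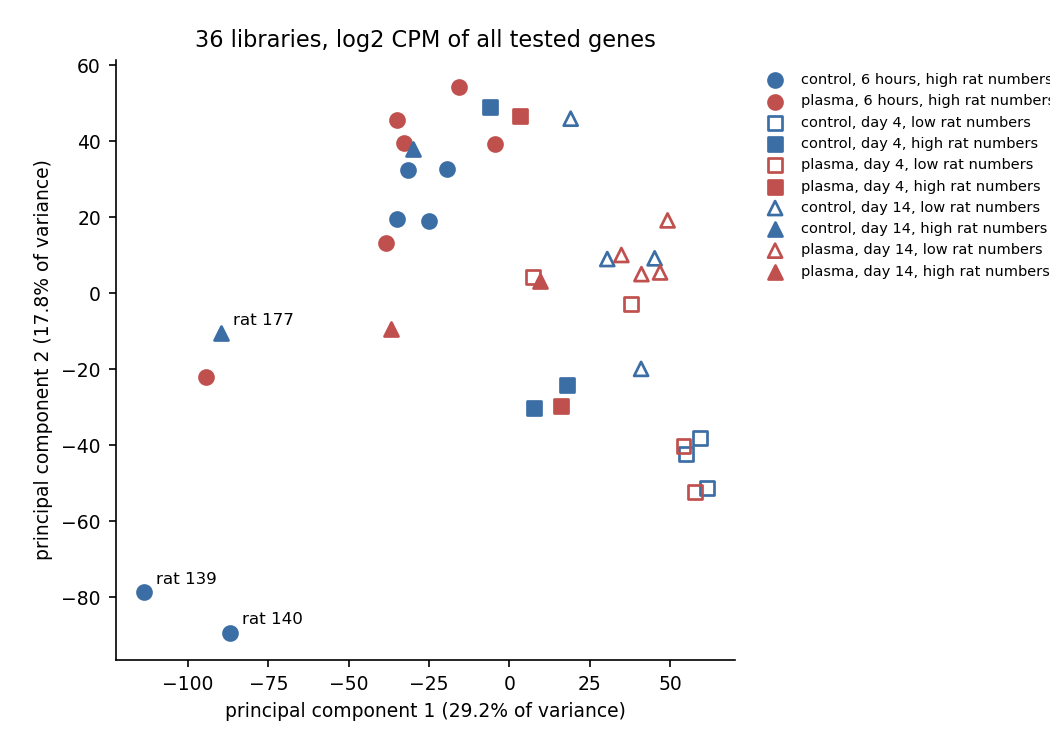
Principal components of the 36 libraries (log2 CPM of the tested genes), PC1 with 29.2% and PC2 with 17.8% of the variance. Colour gives treatment and marker shape gives time, n = 6 per group. Open points are rats of the low number series, filled points rats of the high series, and rats 139, 140 and 177 are labelled.

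What did plasma treatment of a fresh incision do to the muscle within 6 hours? Transcripts of inflammatory cytokines and chemokines, the signals that call leukocytes to a wound, were lower in treated muscle. Of 14 measured members 13 had a negative log2 fold change, with a median of -1.30, and the list shifted down (adjusted p = 1.41e-09 by camera, and adjusted p = 0.16 with an estimated correlation). The median was -1.14 without control rats 139 and 140 (adjusted p = 3.14e-12). Il6, a cytokine of acute inflammation, averaged 1.07 CPM (SD 0.875, n = 6) in treated rats and 3.02 CPM (SD 1.9, n = 6) in controls, a log2 fold change of -1.48 (SE 0.70, adjusted p = 0.598). The monocyte attractant Ccl2 averaged 7.34 CPM (SD 4.95) against 18.2 CPM (SD 7.27), log2 fold change -1.31 (SE 0.48, adjusted p = 0.47). For Il1b the log2 fold change was -1.51 (SE 0.64, adjusted p = 0.546) and for the neutrophil attractant Cxcl1 -1.26 (SE 0.60, adjusted p = 0.598). Those 4 genes did not pass the threshold singly. Without the 2 rats their log2 fold changes were -1.57 (Il6, SE 0.77), -1.35 (Ccl2, SE 0.54), -0.57 (Il1b, SE 0.66) and -1.15 (Cxcl1, SE 0.66). Over the cytokine list alone 0 members passed, as over all genes.

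Other stress and immune lists shifted in the same direction at 6 hours. Immediate early genes, which respond to injury within minutes, had a median of -0.66 (19 of 23 negative, adjusted p = 3.12e-07, and adjusted p = 0.16 with an estimated correlation) and -0.61 without rats 139 and 140. Targets of NF-kB, the transcription factor that switches on inflammatory genes, had a median of -0.30 (16 of 20 negative, adjusted p = 8.18e-06, and adjusted p = 0.16 with an estimated correlation) and -0.25 without the same rats (adjusted p = 6.9e-08). Interferon-response genes, part of antiviral defence, had a median of -0.62 (22 of 23 negative, adjusted p = 4.07e-06, and adjusted p = 0.347 with an estimated correlation) and -0.42 without them (adjusted p = 0.000101). Oxidative-stress genes controlled by NRF2 had a median of -0.29 (19 of 24 negative, adjusted p = 0.000245, and adjusted p = 0.16 with an estimated correlation) and -0.28 without them (adjusted p = 4.83e-07). In these lists 0 members passed over all genes. Adjusted over the list alone, 1 immediate early gene and 2 NF-kB targets passed, all lower, and 0 interferon or NRF2 genes. Neutrophil markers had a median of -0.95 (9 of 10 negative, adjusted p = 0.00186, and adjusted p = 0.347 with an estimated correlation) and -0.42 without the 2 rats (adjusted p = 0.0375). The metallothionein Mt2A, which binds zinc and other metals, averaged 87.3 CPM (SD 54.3) in treated and 209 CPM (SD 125) in control muscle, log2 fold change -1.26 (SE 0.48, adjusted p = 0.49). Hmox1, which breaks down haem, had a log2 fold change of -0.84 (SE 0.61, adjusted p = 0.694), the stress factor Atf3 0.29 (SE 0.42, adjusted p = 0.826). Without rats 139 and 140 the values were -1.09 (Mt2A, SE 0.52), -1.10 (Hmox1, SE 0.67) and 0.41 (Atf3, SE 0.47).

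**Figure D2:**
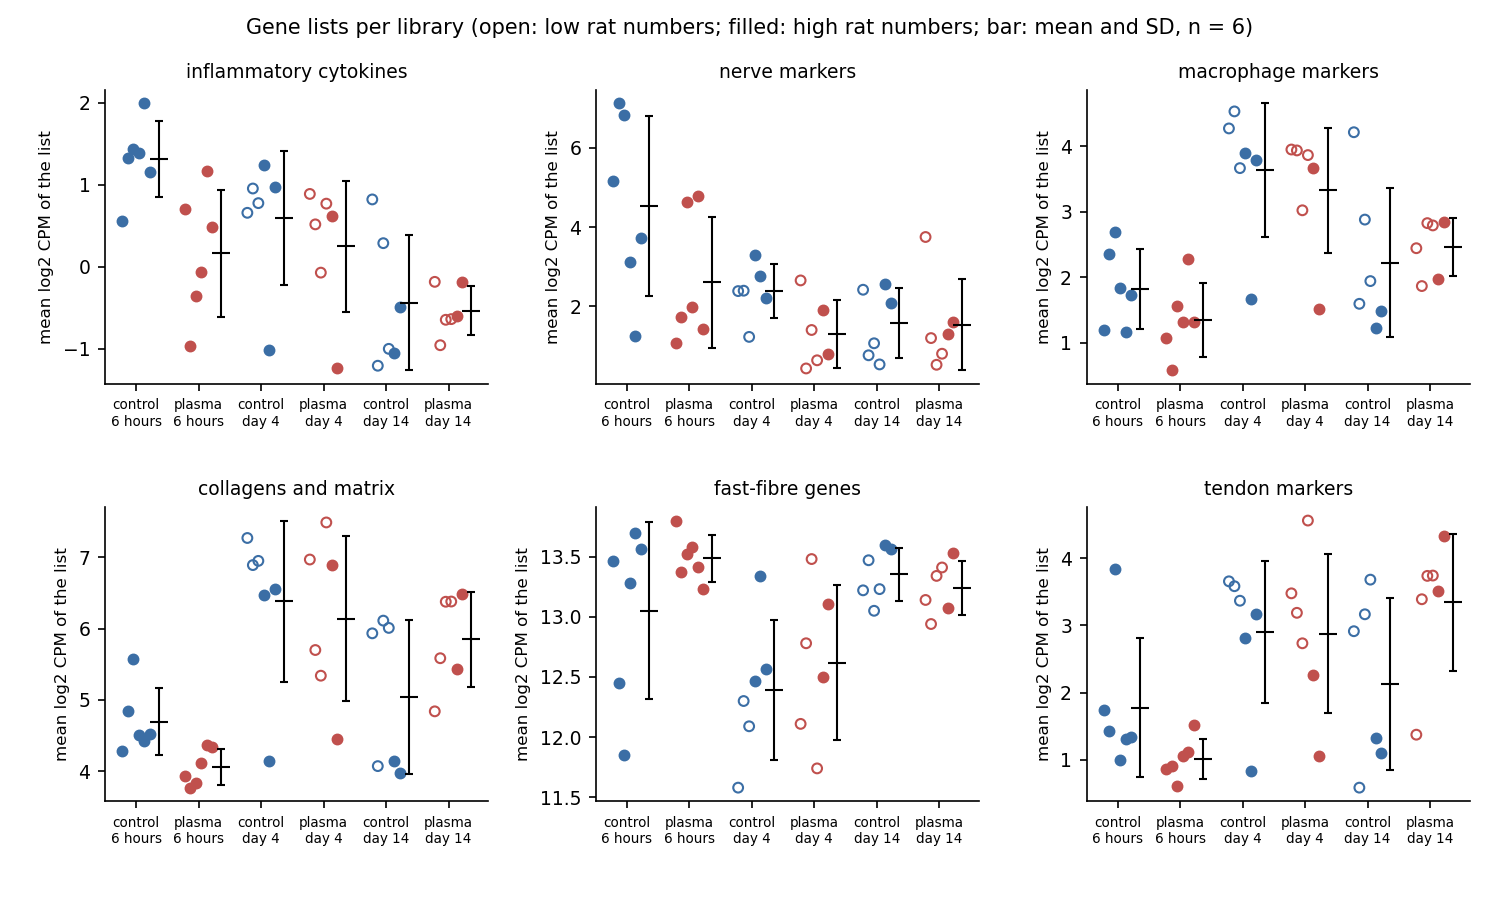
Mean log2 CPM of 6 gene lists in each library, by treatment and time, with mean and SD of each group (n = 6). Open points are rats of the low number series, filled points rats of the high series.

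Matrix and nerve lists also shifted down in treated muscle at 6 hours. Nerve and Schwann cell markers, which build and insulate peripheral nerve, had a median of -2.37 (13 of 13 negative, adjusted p = 2.75e-10, and adjusted p = 0.162 with an estimated correlation). Over all genes 0 of these markers passed, and 11 passed over the list alone. Without rats 139 and 140 the median was -0.66 (adjusted p = 0.00102). The mean log2 CPM of nerve markers was 7.12 in rat 139, 6.82 in rat 140 and 5.17 in rat 138, and 1.07 to 4.77 in the 6 treated rats. The other controls, rats 145 (3.11), 146 (1.26) and 147 (3.72), lay within the treated range. The myelin gene Pmp22 averaged 131 CPM (SD 151) in treated against 815 CPM (SD 952) in control muscle, log2 fold change -2.63 (SE 0.77). Collagens and other matrix genes had a median of -0.59 (28 of 29 negative, adjusted p = 8.18e-06, and adjusted p = 0.497 with an estimated correlation) and -0.36 without the 2 rats (adjusted p = 0.0288). Matrix-remodelling enzymes had a median of -0.57, or -0.55 with a gene of too few counts set at its bound (18 of 19 negative, adjusted p = 2.5e-05, and adjusted p = 0.275 with an estimated correlation), and -0.29 without rats 139 and 140 (adjusted p = 0.000411). Adjusted over the list alone, 2 remodelling genes passed, both lower. Col1a1, the chain of the main scar collagen, averaged 445 CPM (SD 171) against 905 CPM (SD 339), log2 fold change -1.02 (SE 0.64, adjusted p = 0.676). For Timp1, an inhibitor of matrix proteases, the value was -1.28 (SE 0.55, adjusted p = 0.557), and for Spp1, made by macrophages in damaged muscle, -3.02 (SE 1.24, adjusted p = 0.534). Without rats 139 and 140 Col1a1 had a value of -0.68 (SE 0.71), Timp1 -0.96 (SE 0.60) and Spp1 -0.64 (SE 1.22).

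In 7 further lists the downward shift at 6 hours was not called once rats 139 and 140 were left out. Tendon markers had a median of -1.10 (10 of 12 negative, adjusted p = 0.0466, and adjusted p = 0.573 with an estimated correlation; 4 lower over the list alone) and -0.25 without them. TGF-beta and fibrosis genes had a median of -0.33, or -0.41 with 1 gene set at its bound (adjusted p = 0.0107, and adjusted p = 0.546 with an estimated correlation; 2 lower over the list alone), and -0.03 without them. Macrophage markers moved from -0.40 (adjusted p = 0.0411, and adjusted p = 0.704 with an estimated correlation) to -0.05, and endothelial markers from -0.31 (adjusted p = 0.00143, and adjusted p = 0.497 with an estimated correlation) to 0.09. Acute-phase genes moved from -0.27 (adjusted p = 0.0263, and adjusted p = 0.573 with an estimated correlation) to -0.08, and angiogenic factors from -0.33 (adjusted p = 0.0143, and adjusted p = 0.16 with an estimated correlation) to -0.25. Fibro-adipogenic progenitor markers moved from -0.27 (adjusted p = 0.00934, and adjusted p = 0.43 with an estimated correlation) to -0.17. The macrophage genes Cd68 and Mrc1 had log2 fold changes of -0.10 (SE 0.53) and -0.21 (SE 0.39), and of 0.41 (SE 0.58) and 0.35 (SE 0.42) without those rats.

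Lists of muscle fibre and energy genes shifted up in treated muscle at 6 hours, with 0 members called singly. The citrate cycle and fatty acid oxidation list, which feeds mitochondrial respiration, had a median of 0.51 (26 of 27 positive, adjusted p = 3.45e-14, and adjusted p = 0.16 with an estimated correlation) and 0.16 without rats 139 and 140 (adjusted p = 0.00747). Oxidative phosphorylation genes had a median of 0.42 (27 of 29 positive, adjusted p = 1.92e-11, and adjusted p = 0.248 with an estimated correlation) and 0.11 without them (adjusted p = 0.0184). Slow fibre genes had a median of 0.37 (13 of 17 positive, adjusted p = 4.78e-05, and adjusted p = 0.43 with an estimated correlation) and 1.47 without them (adjusted p = 2e-16). Glycolysis genes had a median of 0.36 (adjusted p = 1.94e-08, and adjusted p = 0.275 with an estimated correlation), sarcomere genes 0.37 (adjusted p = 4.19e-08, and adjusted p = 0.162 with an estimated correlation) and fast fibre genes 0.25 (adjusted p = 4.96e-05, and adjusted p = 0.43 with an estimated correlation). Without the 2 rats these 3 medians were 0.01, 0.03 and 0.00 and the lists were not called. Y-linked genes had a median of 0.25 (5 of 5 positive, adjusted p = 0.0101, and adjusted p = 0.16 with an estimated correlation; 1 higher over the list alone) and 0.24 without them (3 of 5 positive, adjusted p = 0.00111). In total 23 of the 41 lists shifted at 6 hours, 7 up and 16 down. Fbxo32, a ubiquitin ligase of muscle atrophy, averaged 120 CPM (SD 67.7) in treated and 52.7 CPM (SD 30.7) in control muscle, log2 fold change 1.18 (SE 0.49, adjusted p = 0.544). The slow myosin Myh7 had a log2 fold change of 1.10 (SE 0.93) and skeletal actin Acta1 0.37 (SE 0.31). Without rats 139 and 140 these values were 0.74 (SE 0.50) for Fbxo32, 2.20 (SE 1.07) for Myh7 and -0.01 (SE 0.27) for Acta1.

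A single gene passed the threshold at 6 hours, Mif, which encodes a cytokine that keeps macrophages at a site of inflammation. It averaged 0.757 CPM (SD 0.301, n = 6) in treated and 13.2 CPM (SD 13.9, n = 6) in control rats, a log2 fold change of -4.10 (SE 0.73, 95% interval -5.53 to -2.66, adjusted p = 0.0399). Control rats 138, 139 and 146 held 23.9 to 27 CPM of Mif, and the other 33 libraries of the series 0.19 to 1.43 CPM, untreated rats among them. The call was lost without control rat 138 (adjusted p = 0.0963), 139 (0.159) or 146 (0.0562), and without treated rat 136 (0.0779), 137 (0.108), 141 (0.0879), 143 (0.196), 144 (0.092) or 148 (0.0977). It was also lost without control rats 35 (0.0559), 64 (0.056) or 195 (0.0552) of day 4, or 65 (0.053) of day 14, although these rats are not in the comparison. The same held for treated rats 18 (0.0551), 49 (0.0556), 66 (0.0545), 51 (0.0533), 131 (0.0532) and 132 (0.055) of day 4, and 22 (0.0562), 62 (0.0534) and 67 (0.0519) of day 14. Over the 36 fits that left out 1 library the log2 fold change stayed between -4.35 and -3.75. At unadjusted p under 0.05, edgeR counted 1172 genes, a number that 17 of 100 groupings of the rats reached. DESeq2 called 32 genes (3 higher, 29 lower) and voom 7 (3 higher, 4 lower). By voom Mif was not called, at -1.45 (SE 0.89, adjusted p = 0.618). Without rats 139 and 140 the log2 fold change of Mif was again -4.10 (SE 0.68, adjusted p = 0.0135) and a 2nd gene passed, LOC100912571 at -2.99 (SE 0.54, adjusted p = 0.0259).

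At day 4 the question was whether plasma altered the tissue while inflammation and repair were under way. Interferon-response genes were higher in treated muscle, with a median log2 fold change of 0.41 (21 of 23 positive, adjusted p = 1.36e-05, and adjusted p = 0.802 with an estimated correlation). Their median was 0.74 among rats of the low number series and -0.19 among rats of the high series. At day 4 the low series holds 3 control and 4 treated rats, the high series 3 control and 2 treated rats. Control rat 193 and treated rat 132, both low in macrophage markers, are in the high series. Medians within the series at day 4 thus rest on few rats. The antiviral genes Oas1a, Mx2 and Usp18, chosen after their values were seen, had log2 fold changes of 1.63 (SE 0.64), 1.45 (SE 0.60) and 1.04 (SE 0.43), each with an adjusted p of 1. Nerve markers were lower, with a median of -0.98 (13 of 13 negative, adjusted p = 1.67e-05, and adjusted p = 0.802 with an estimated correlation), -0.39 in the low and -1.71 in the high series. Cell-cycle genes, a mark of dividing cells, had a median of -0.22 (20 of 29 negative, adjusted p = 1.67e-05, and adjusted p = 0.802 with an estimated correlation), -0.44 in the low and 0.08 in the high series. Neutrophil markers had a median of -0.40 (7 of 10 negative, adjusted p = 9.95e-05, and adjusted p = 0.802 with an estimated correlation), -0.38 and -1.11 within the series.

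Of the remaining shifts at day 4, 5 were downward and 3 upward. Immediate early genes had a median of -0.20 (adjusted p = 0.000844, and adjusted p = 0.802 with an estimated correlation), -0.26 in the low and -0.44 in the high series. Macrophage markers had a median of -0.21 (22 of 24 negative, adjusted p = 0.00366, and adjusted p = 0.803 with an estimated correlation), -0.37 and -0.34 within the series. Endothelial markers had a median of -0.19 (adjusted p = 0.00796), TGF-beta genes -0.21 (adjusted p = 0.042) and matrix-remodelling genes -0.11 (adjusted p = 0.0152), each with adjusted p = 0.802 with an estimated correlation. Within the low and high series these medians were -0.26 and 0.00, -0.39 and -0.15, and -0.35 and -0.07. With a term for the series the endothelial shift was lost (adjusted p = 0.097) and collagens were called lower (median -0.17, adjusted p = 0.0153). Fast fibre genes, which drive rapid contraction, had a median of 0.27 (16 of 16 positive, adjusted p = 0.00722), oxidative phosphorylation genes 0.14 (29 of 29 positive, adjusted p = 0.000448), each with adjusted p = 0.802 with an estimated correlation. Glycolysis genes had a median of 0.20 (adjusted p = 0.0436, and adjusted p = 0.883 with an estimated correlation). Their medians in the low and high series were 0.77 and -0.04, 0.66 and -0.16, and 0.48 and 0.04. In each list 0 members passed, over all genes or over the list alone. Left-out libraries moved the number of shifted lists from 12 to 6 (control rat 17), 19 (control rat 193) or 4 (treated rat 132). The mean log2 CPM of macrophage markers was 1.52 in rat 132, against 3.02 to 3.95 in the other treated rats of day 4. It was 1.66 in rat 193, against 3.67 to 4.53 in the other controls of day 4.

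No single gene passed at day 4. The count was 0 by edgeR, with 177 genes at unadjusted p under 0.05, and 0 by DESeq2 and by voom. Within the low series it was 0 and within the high series 0. Il6 averaged 0.152 CPM (SD 0.154) in treated and 0.547 CPM (SD 0.261) in control rats, log2 fold change -1.79 (SE 0.77). Hmox1 averaged 41.9 CPM (SD 33.4) against 78.8 CPM (SD 49.6), log2 fold change -0.91 (SE 0.61). For Il1b the value was -0.93 (SE 0.63), for the repair-macrophage enzyme Arg1 -0.81 (SE 0.70), and for the embryonic myosin Myh3, a mark of regenerating fibres, 1.33 (SE 0.93). Col1a1 (-0.17, SE 0.64) and Cd68 (-0.11, SE 0.49) were near 0. Each of these genes had an adjusted p of 1.

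At day 14, when scar tissue forms, lists of matrix genes shifted upward in treated muscle by camera at its preset correlation, and by no other list test. Collagens and related genes had a median log2 fold change of 0.53 (28 of 29 positive, adjusted p = 5.67e-11, and adjusted p = 0.996 with an estimated correlation), 0.20 in the low and 1.96 in the high number series. Tendon markers, expressed where muscle meets dense connective tissue, had a median of 1.10 (12 of 12 positive, adjusted p = 3.02e-07, and adjusted p = 0.826 with an estimated correlation), 0.26 in the low and 3.26 in the high series. Col1a1 averaged 2150 CPM (SD 1420, n = 6) in treated and 1200 CPM (SD 1030, n = 6) in control rats, log2 fold change 0.84 (SE 0.64, adjusted p = 1), with 0.40 in the low and 3.06 in the high series. Col3a1, the collagen of early scars, had a log2 fold change of 0.50 (SE 0.42), 0.12 and 1.67 within the series. The high series holds 2 rats per group at day 14, and its controls are rats 133 and 177, the latter standing apart from its group. The mean log2 CPM of collagens was 4.14 in rat 133, 3.98 in rat 177 and 4.07 in control rat 41. The other controls held 5.93 to 6.11, within the range of treated rats (4.84 to 6.48). For tendon markers these 3 controls held 1.33, 1.10 and 0.58, the others 2.91 to 3.68 and treated rats 1.37 to 4.33. Control rats 41, 133 and 177 thus lay below all treated rats in both lists.

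Cell-cycle genes at day 14 had a median of 0.29 (19 of 29 positive, adjusted p = 0.00461, and adjusted p = 0.996 with an estimated correlation), 0.12 in the low and 0.57 in the high series. TGF-beta genes, which drive scarring, had a median of 0.28 (19 of 20 positive, adjusted p = 0.00136, and adjusted p = 0.996 with an estimated correlation), 0.11 and 1.19 within the series. Matrix-remodelling genes had a median of 0.15 (13 of 19 positive, adjusted p = 0.0077, and adjusted p = 0.996 with an estimated correlation), 0.00 and 0.98 within the series. Oxidative phosphorylation genes had a median of -0.15 (25 of 29 negative, adjusted p = 0.0077, and adjusted p = 0.996 with an estimated correlation), -0.07 and -0.28 within the series. In the 6 lists 0 members passed, over all genes or over the list alone. Without control rat 133, 3 lists were left, and the TGF-beta, matrix-remodelling and oxidative phosphorylation shifts were lost. Without control rat 177, which stands apart from its group, 5 lists were called, 4 of the 6 and 1 other, and the TGF-beta and matrix-remodelling shifts were lost. By edgeR 0 genes passed, with 328 at unadjusted p under 0.05. DESeq2 and voom called 0, and 0 passed within the low or the high series. Cxcl1 had a log2 fold change of -1.33 (SE 0.72), Vegfa, the main vessel growth factor, -0.73 (SE 0.39) with -0.30 and -1.06 within the series, and the satellite cell gene Pax7 -0.82 (SE 0.61).

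**Figure D3:**
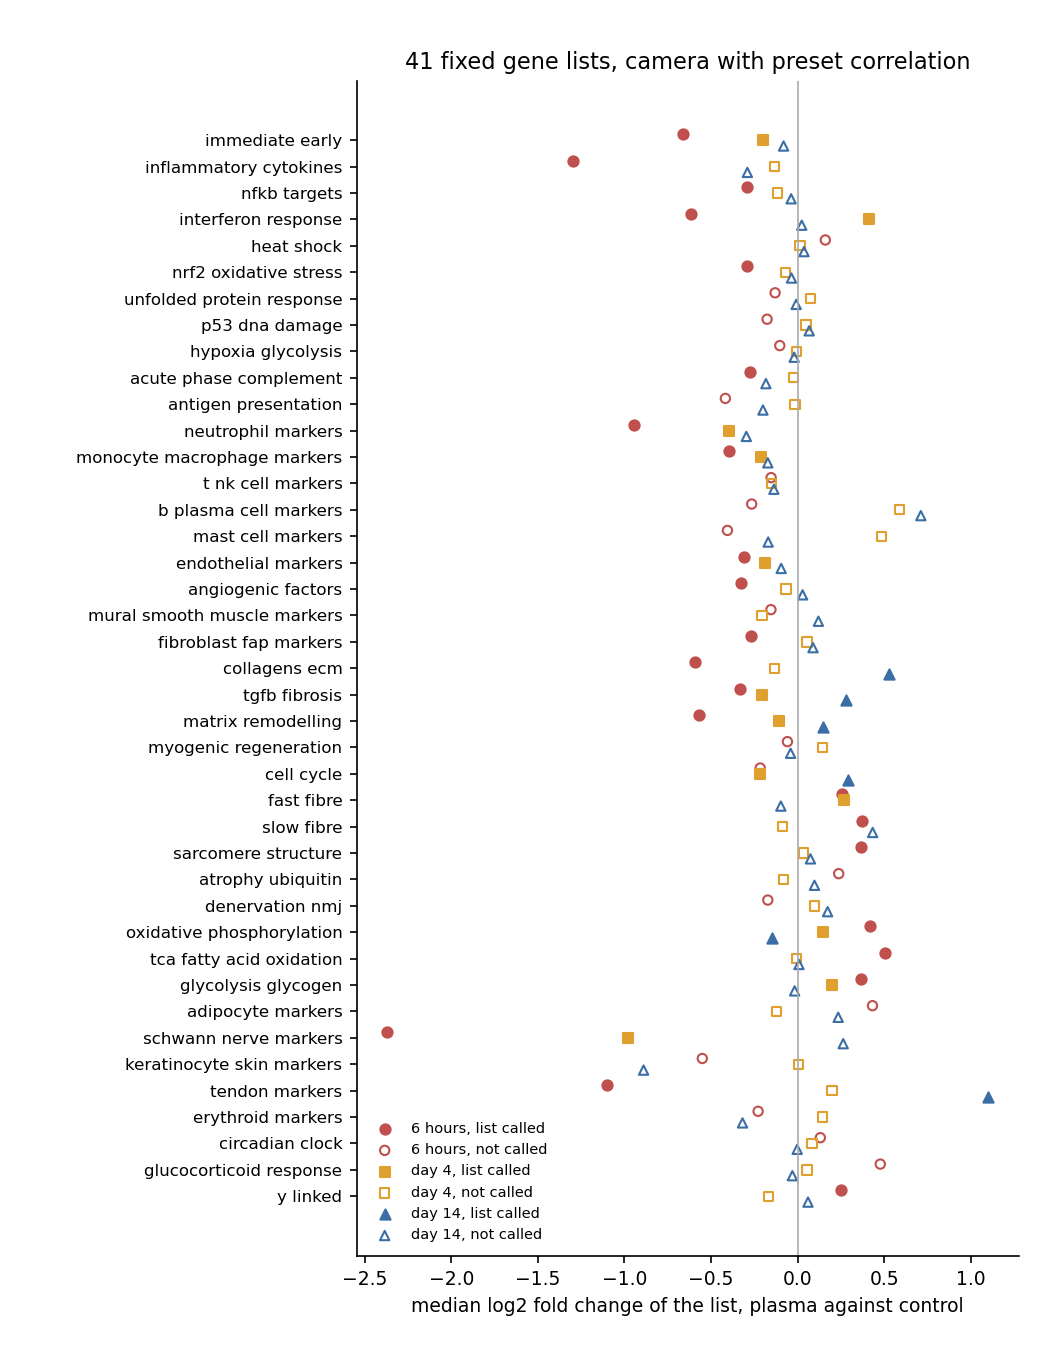
Median log2 fold change of treated over control muscle for the 41 gene lists at 6 hours, day 4 and day 14. Filled points mark lists called by camera with its preset correlation, from 6 rats per group.

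Did the response to plasma differ between times? Interferon-response genes, lower at 6 hours and higher at day 4, had a median difference of 1.01 between the plasma effects at day 4 and 6 hours (adjusted p = 1.52e-12, and adjusted p = 0.494 with an estimated correlation), with 2 members called over the list alone and 0 over all genes. Cytokine genes had a median difference of 0.92 (adjusted p = 0.000718, and adjusted p = 0.52 with an estimated correlation), and citrate cycle and fatty acid oxidation genes -0.50 (adjusted p = 2.13e-10, and adjusted p = 0.52 with an estimated correlation). From day 4 to day 14 the effect on collagens rose by a median of 0.60 (adjusted p = 2.98e-08, and adjusted p = 0.976 with an estimated correlation). The effect on cell-cycle genes rose by 0.39 (adjusted p = 1.49e-06, and adjusted p = 0.976 with an estimated correlation; 1 member over the list alone). The effect on interferon genes fell by 0.44 (adjusted p = 0.00112, and adjusted p = 0.976 with an estimated correlation). For neutrophil markers the median difference was 0.07, the mean -0.02 and the list test upward (adjusted p = 0.0364, and adjusted p = 0.976 with an estimated correlation). All 6-hour rats are in the high series, and within that series the median differences between day 4 and 6 hours were 0.35 for interferon, 0.45 for cytokine and -0.64 for citrate cycle genes. Between day 14 and day 4 they were 1.70 for collagens, 0.45 for cell-cycle genes and 0.585 for interferon genes, the last of opposite sign to the value over all rats. The high series holds only 3 control and 2 treated rats at day 4, and 2 of each at day 14. In total 15 lists differed between 6 hours and day 4, and 10 between day 4 and day 14.

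For single genes, the joint test over the 3 times called 0 genes by edgeR, with 448 at unadjusted p under 0.05, 1 by DESeq2 and 1 by voom. Day 4 against 6 hours gave 0 genes (436 at unadjusted p under 0.05; 4 by DESeq2, 1 by voom), and day 14 against day 4 gave 0 (275 at unadjusted p under 0.05; 0 by DESeq2 and voom). Without treated rat 137 at 6 hours, 1 gene passed the joint test and 1 the first contrast. Across the 14154 genes, which are not independent replicates, plasma effects at 6 hours and day 4 correlated with r = 0.125 and shared their sign in 57.5% of genes. The correlation across genes was -0.0577 between 6 hours and day 14 and -0.0483 between day 4 and day 14.

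How the incision itself changed with time was read from the untreated controls, where macrophage, matrix and cell-division genes rose from 6 hours to day 4 and nerve and fast fibre genes fell. Macrophage markers rose by a median log2 fold change of 1.84 (adjusted p = 6.52e-10, and adjusted p = 0.573 with an estimated correlation; 1.35 in rats of the high series), with 17 of 24 genes called higher over all genes and 20 over the list alone. Csf1r, the receptor for the macrophage growth factor, rose by 1.80 (SE 0.36, adjusted p = 0.00249), Adgre1 by 3.01 (SE 0.61, adjusted p = 0.00257) and Mrc1 by 1.69 (SE 0.39, adjusted p = 0.0062). Cd68 rose from 3.67 CPM (SD 2.39, n = 6) to 17.2 CPM (SD 9.61, n = 6), log2 fold change 2.25 (SE 0.53, adjusted p = 0.00636), and Arg1 rose by 3.30 (SE 0.83, adjusted p = 0.01). Collagens and matrix genes rose by a median of 1.73 (adjusted p = 2.19e-09, and adjusted p = 0.573 with an estimated correlation; 1.17 in the high series), with 21 of 29 called over all genes and 22 over the list alone. The wound matrix gene Tnc rose from 4.41 CPM (SD 2.52) to 205 CPM (SD 127), log2 fold change 5.54 (SE 0.96, adjusted p = 0.000771). Cthrc1, secreted by activated fibroblasts, rose by 5.60 and the myofibroblast gene Adam12 by 4.31. Col1a1 rose from 905 CPM (SD 339) to 3940 CPM (SD 2150), log2 fold change 2.12 (SE 0.66, adjusted p = 0.0293), a call lost without control rat 17 (adjusted p = 0.0721) or 64 (0.0594). Cell-cycle genes rose by a median of 1.33 (adjusted p = 2.31e-05, and adjusted p = 0.573 with an estimated correlation; 0.83 in the high series), with 10 of 29 called and 17 over the list alone. The mitotic kinase Aurkb rose by 2.14 (SE 0.48, adjusted p = 0.00467) and the nucleotide synthesis gene Rrm2 by 3.50 (SE 0.90, adjusted p = 0.0116). Mki67 was not called (1.45, adjusted p = 0.0515).

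The largest rise in controls from 6 hours to day 4 was that of Tnn, a matrix protein of the tenascin family, with 0 counts in the 6 libraries at 6 hours and 122 CPM (SD 92.3) at day 4, at least 4450-fold higher (adjusted p = 0.00131). The fibroblast membrane gene Lrrc15 likewise went from 0 counts to 7.55 CPM (SD 6.17), at least 273-fold higher (adjusted p = 0.00745). Clec2dl1, a lectin gene with 1 count at 6 hours, had a ratio of 1080 (95% counting interval 194 to 42700, adjusted p = 0.00101). The protease-like Prss35 had 3 counts and a ratio of 264 (90.1 to 1280, adjusted p = 0.00209). The macrophage elastase Mmp12 rose by 6.44 (SE 2.01, adjusted p = 0.0308). That call was lost without control rat 139 (adjusted p = 0.0605), 145 (0.0536), 146 (0.0542) or 147 (0.0547) at 6 hours, or 17 (0.0656), 35 (0.0504) or 64 (0.0511) at day 4. Mif fell by 5.14 (SE 0.77, adjusted p = 0.000151), from 23.9 to 27 CPM in 3 of the 6 rats at 6 hours, while the other 3 held 0.429 to 0.546 CPM and day 4 controls 0.19 to 0.639 CPM, and the cadherin Cdh16 from 10.8 CPM (SD 6.2) to 0.329 CPM (SD 0.176), log2 fold change -4.98 (SE 0.92, adjusted p = 0.00131). Pmp2, a myelin protein, fell by 4.94 (SE 1.40, adjusted p = 0.0193), lost without rat 139 (adjusted p = 0.0646) or 64 (0.0509). The cartilage gene Lect1 fell by 4.68 (SE 1.31, adjusted p = 0.0176), lost without rat 139 (adjusted p = 0.0587), and Fam111a by 4.34 (SE 1.21, adjusted p = 0.0176), lost without rat 140 (adjusted p = 0.112).

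Cytokine transcripts fell in controls by day 4. Cytokine genes fell by a median of 1.11 (adjusted p = 0.0052, and adjusted p = 0.573 with an estimated correlation), with 4 members lower and 2 higher, the same over the list alone. Cxcl1 fell by 3.60 (SE 0.66, adjusted p = 0.00125), Ccl2 by 1.66 (SE 0.48, adjusted p = 0.0224) and Socs3, which brakes cytokine signalling, from 67.4 CPM (SD 25.2) to 8.34 CPM (SD 2.44), log2 fold change -3.02 (SE 0.44, adjusted p = 0.00012). The immediate early gene Junb fell by 2.49 (SE 0.31, adjusted p = 2.05e-05), while the immediate early list did not shift (median -0.12, adjusted p = 0.124) and Fos (0.38, SE 0.37) and Atf3 (0.72, SE 0.42) had positive values. Mt2A fell by 3.25 (SE 0.52, adjusted p = 0.000349). Il6 fell by 2.43 (SE 0.72, adjusted p = 0.0232), lost without control rat 146 (adjusted p = 0.0673), 17 (0.0509) or 64 (0.0548). Interferon genes fell by a median of 0.98 (adjusted p = 5.31e-05, and adjusted p = 0.573 with an estimated correlation; -0.86 in the high series), with 5 of 23 lower and 12 over the list alone. Endothelial markers fell by 0.63 (adjusted p = 0.00297, and adjusted p = 0.573 with an estimated correlation; -0.56 in the high series), with 9 of 22 lower and 0 higher, or 11 and 2 over the list alone. The medians were -0.82 for cytokine, -0.69 for interferon and -0.27 for endothelial genes (10 of 22 positive) without rats 139 and 140. Nerve markers fell by a median of 3.38 (adjusted p = 2.31e-05, and adjusted p = 0.573 with an estimated correlation; -2.98 in the high series), with 12 of 13 called, and 12 over the list alone. Pmp22 fell by 3.62 (SE 0.80, adjusted p = 0.00441), next to the high nerve scores of control rats 138, 139 and 140, and without the last 2 the median of the list was -1.44. Fast fibre genes fell by a median of 0.59 (adjusted p = 0.000881, and adjusted p = 0.573 with an estimated correlation; -0.28 in the high series), with 7 of 16 called, 7 over the list alone. The fast myosin light chain Mylpf fell from 19700 CPM (SD 4640) to 6980 CPM (SD 3530), log2 fold change -1.50 (SE 0.33, adjusted p = 0.0042).

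Of the 41 lists 17 shifted in controls over this interval, 8 up and 9 down, and fry called 7. In total 2160 genes changed in controls between 6 hours and day 4, 1034 higher and 1126 lower. Without control rat 139 at 6 hours 1048 genes passed. Without control rats 17, 35, 64 or 193 at day 4 the counts were 976, 1201, 1026 and 2793. All 6-hour rats are in the high series, and a contrast within that series called 161 genes, while 593 passed with a term for the series. The high series holds 3 of the 6 controls of day 4, rat 193 among them.

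From day 4 to day 14 matrix, macrophage and cell-division lists shifted down in controls, and fast fibre and respiration lists up. Collagens fell by a median log2 fold change of 1.17 (28 of 29 negative, adjusted p = 2.89e-11, and adjusted p = 0.378 with an estimated correlation), by 1.31 in the low and 2.03 in the high series, with 1 member called and 19 over the list alone. Macrophage markers fell by 1.12 (adjusted p = 1.51e-11, and adjusted p = 0.378 with an estimated correlation), by 1.13 and 1.86 within the series, with 0 called and 7 over the list alone. Cell-cycle genes fell by 1.17 (adjusted p = 1.44e-09, and adjusted p = 0.378 with an estimated correlation), by 1.40 and 0.99 within the series, with 1 called and 12 over the list alone. Fast fibre genes rose by 0.92 (adjusted p = 1.51e-11, and adjusted p = 0.378 with an estimated correlation), by 1.29 and 0.51 within the series, with 4 called and 9 over the list alone. Oxidative phosphorylation genes rose by 0.78 (adjusted p = 2.01e-15, and adjusted p = 0.378 with an estimated correlation), by 1.13 and 0.69 within the series, with 0 called and 21 over the list alone.

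Of the 41 lists 19 shifted, 6 up and 13 down, and fry called 3. Among single genes, Mylpf rose from 6980 CPM (SD 3530) to 21100 CPM (SD 8180), log2 fold change 1.59 (SE 0.33, adjusted p = 0.0217). Nmrk2, which makes NAD in muscle, rose by 2.12 (SE 0.46, adjusted p = 0.0218), with Trpm1 at 1.69 (SE 0.35, adjusted p = 0.0217), Fam71e1 at 1.63 (SE 0.32, adjusted p = 0.0217) and A930016O22Rik at 1.96 (SE 0.44, adjusted p = 0.0267). The lipid synthesis gene Thrsp fell by 3.71 (SE 0.66, adjusted p = 0.0167), the fibroblast gene Sfrp2 by 3.22 (SE 0.67, adjusted p = 0.0217) and Hmox1 from 78.8 CPM (SD 49.6) to 9.19 CPM (SD 7.43), log2 fold change -3.09 (SE 0.66, adjusted p = 0.0217). MGC114427 fell by 2.84 (SE 0.70, adjusted p = 0.0409). Aurkb fell by 2.25 (SE 0.47, adjusted p = 0.0217) and Prg4, which encodes lubricin, by 1.53. Without control rat 17, 35, 64, 126 or 177 these calls were lost, with adjusted p up to 0.0863 for Mylpf, Nmrk2, Trpm1, Sfrp2 and Aurkb, 0.0862 for Hmox1 and Prg4, 0.0847 for Fam71e1, 0.14 for A930016O22Rik and 0.121 for MGC114427. Without control rat 133 of day 14 the calls of Mylpf, Nmrk2, Sfrp2, Hmox1, A930016O22Rik and MGC114427 were lost too, that of MGC114427 also without control rats 41 or 65. The call of Thrsp was lost without rat 64 (adjusted p = 0.0511), 126 (0.0512) or 177 (0.0747). In all, 104 genes changed, 61 higher and 43 lower, with 120 in the low and 19 in the high series. Without control rats 17, 35, 64, 126 or 193 of day 4 the counts were 2, 2, 1, 1 and 918. Without control rats 21, 41, 65, 47, 133 or 177 of day 14 they were 379, 62, 56, 261, 21 and 0, and without treated rat 132 of day 4 it was 192.

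The same contrasts in treated rats were added after the data were seen. From 6 hours to day 4, collagens rose by a median log2 fold change of 2.36 (adjusted p = 2.56e-15, and adjusted p = 0.471 with an estimated correlation), with 23 of 29 called and 27 over the list alone. Macrophage markers rose by 2.19 (adjusted p = 2.61e-11, and adjusted p = 0.471 with an estimated correlation), with 18 of 24 called and 22 over the list alone. Tendon markers rose by 1.67 (adjusted p = 0.000174, and adjusted p = 0.471 with an estimated correlation), with 8 of 12 called and 10 over the list alone. Oxidative phosphorylation genes fell by 0.76 (adjusted p = 4.64e-11, and adjusted p = 0.471 with an estimated correlation), with 15 of 29 called and 19 over the list alone. In total 1521 genes changed, 969 higher and 552 lower. All treated rats of 6 hours and 2 of the 6 of day 4 are in the high series, and 214 genes passed with a term for the series and 28 within the high series. Without treated rats 136 or 143 of 6 hours, 877 and 933 genes passed, and without treated rats 18, 66 or 132 of day 4, 722, 665 and 2189. Control and treated rats shared 506 rises and 326 falls, against 70.8 and 43.9 if the calls were independent, and 0 genes moved in opposite directions. Both contrasts also set high-series rats against groups with low-series rats. With a term for the series they shared 87 rises and 31 falls (2.72 and 1.4 if independent), and within the high series 15 and 2. Of the 2160 genes called in controls, 98.2% had the same sign in treated rats, and the log2 fold changes correlated across genes, which are not independent replicates, with r = 0.776. From day 4 to day 14 edgeR called 0 genes in treated rats, with 967 at unadjusted p under 0.05, 4 by DESeq2 and 30 by voom. All 104 genes called in controls had the same sign there.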

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

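The comparisons in this part follow fixed rules, while the link to rat numbers was chosen only after the result was seen. Of 210 group values checked, in 35 measures, 24 held a rat far from the other 5 of its group by Dixon's ratio, and chance flags about 1 in 20 groups (10.5 here). Of these, 11 belong to control rat 193 at day 4, each time the lowest of its group: Il6 (ratio 0.718), Ccl2 (0.815), Hmox1 (0.648), Arg1 (0.737), Spp1 (0.642), Mki67 (0.665), Col1a1 (0.761), Col3a1 (0.742), Tgfb1 (0.841), Acta2 (0.631) and Timp1 (0.781). Col1a1 stood at 8.42 log2 CPM in this rat and at a median of 12.1 in the other 5. At day 4 the treated rat 132 was lowest for Cd68 (0.698). At 6 hours control rat 140 was highest for Myh3 (0.641) and lowest for Trim63 (0.648), and treated rat 148 was highest for Ppargc1a (0.779). Mitochondrial transcripts took 24% of counts in treated rat 141 at 6 hours against a median of 10.9% in the others (0.686), and 29.1% in control rat 177 at day 14 against 12.4% (0.953). Rat 177 was also lowest for Myh7 (0.734). Among other controls at day 14, rat 133 was highest for Myod1 (0.765), rat 41 lowest for Mki67 (0.629) and rat 47 highest for Ppargc1a (0.733). Among treated rats at day 14, rat 135 was highest for Mki67 (0.716) and Vegfa (0.804), and rat 14 for the nerve markers (0.662). The cause was not tested.

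The plasma effect on 15 lists differed between day 4 and 6 hours. Upward differences were those of immediate early genes (median 0.38, adjusted p = 0.0272, and adjusted p = 0.773 with an estimated correlation), cytokines (adjusted p = 0.000718), NF-kB targets (0.30, adjusted p = 0.00593, and adjusted p = 0.52 with an estimated correlation), interferon genes (adjusted p = 1.52e-12) and NRF2 genes (0.35, adjusted p = 0.00926, and adjusted p = 0.494 with an estimated correlation). Collagens (0.50, adjusted p = 0.0138, and adjusted p = 0.85 with an estimated correlation) and matrix-remodelling genes (0.44, adjusted p = 0.0346, and adjusted p = 0.782 with an estimated correlation) also differed upward. Downward differences were those of slow fibre genes (-0.41, adjusted p = 9.56e-05, and adjusted p = 0.617 with an estimated correlation), sarcomere genes (-0.33, adjusted p = 4.61e-05, and adjusted p = 0.52 with an estimated correlation), atrophy genes (-0.31, adjusted p = 0.0166, and adjusted p = 0.773 with an estimated correlation) and oxidative phosphorylation (-0.29, adjusted p = 0.000801, and adjusted p = 0.773 with an estimated correlation). So were citrate cycle genes (adjusted p = 2.13e-10), glycolysis genes (-0.18, adjusted p = 0.00104, and adjusted p = 0.773 with an estimated correlation), adipocyte markers (-0.64, adjusted p = 0.0346, and adjusted p = 0.578 with an estimated correlation) and Y-linked genes (-0.42, adjusted p = 0.0166, and adjusted p = 0.494 with an estimated correlation).

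Between day 14 and day 4 the effect on 10 lists differed, each with adjusted p = 0.976 with an estimated correlation. Upward were collagens (adjusted p = 2.98e-08), cell-cycle genes (adjusted p = 1.49e-06), TGF-beta genes (median 0.48, adjusted p = 0.000177), matrix-remodelling genes (0.37, adjusted p = 0.000406), tendon markers (0.67, adjusted p = 0.000406), nerve markers (1.26, adjusted p = 0.016) and neutrophil markers (adjusted p = 0.0364). Downward were interferon genes (adjusted p = 0.00112), fast fibre genes (-0.32, adjusted p = 0.00644) and oxidative phosphorylation (-0.31, adjusted p = 2.87e-05).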

How the results depend on the processing

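The rat-number series, the omission of 3 libraries standing apart, the omission of control rats 139 and 140 and the surrogate variables were chosen only after the result was seen. No paired analysis was possible because the 36 libraries carry 36 distinct rat numbers, so no rat is in more than 1 group. Shifts of lists rest on the preset correlation of 0.01: with an estimated correlation 0 lists were called at 6 hours, 0 at day 4 and 0 at day 14, and by fry 0, 0 and 0. At 6 hours an adjusted p of 0.01 left 0 genes, DESeq2 called 32, voom 7, the 12 libraries alone 0 and the high series alone 0. Without the 3 libraries standing apart 2 genes passed, and 2 without rats 139 and 140, where 15 lists were called, 13 of the 23 and 2 others. The others were adipocyte markers, higher (median 0.68, adjusted p = 1.54e-05 by camera), and p53 and DNA damage genes, lower (-0.18, adjusted p = 0.0442 by camera). Joint differences among times were 1 by DESeq2 and 1 by voom, and day 4 against 6 hours gave 4 and 1. Scaling by library size moved the median of all genes to -0.131 at 6 hours and to 0.147 in the difference between day 14 and day 4. Agreement across genes with log2 CPM above 1 was 0.165 for 6 hours with day 4 and -0.0806 for day 4 with day 14. The cause was not tested.

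In controls from 6 hours to day 4 the count was 471 at an adjusted p of 0.01, 1242 with a log2 fold change of at least 1, 5913 by voom, 593 with a series term (245 higher, 348 lower), 161 in the high series, 1114 without rats 139 and 140 (688 higher, 426 lower) and 741 with 2 surrogate variables (442 higher, 299 lower). By library size it was 4976 (4525 higher, 451 lower, median of all genes 0.442). From day 4 to day 14 it was 0 at an adjusted p of 0.01, 68 with a log2 fold change of at least 1, 53 without filter, 531 by DESeq2, 1200 by voom, 1 with 12 libraries, 923 with a series term (584 higher, 339 lower), 19 in the high series, 21 without the 3 libraries apart, 240 without rats 139 and 140 and 719 with 2 surrogate variables. By library size it was 3238 (73 higher, 3165 lower, median -0.471).

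In treated rats from 6 hours to day 4 the count was 412 at an adjusted p of 0.01, 911 with a log2 fold change of at least 1, 3668 by voom, 214 with a series term (157 higher, 57 lower), 28 in the high series, 2702 without the 3 libraries apart and 233 with 2 surrogate variables. By library size it was 4896 (4726 higher, 170 lower, median 0.498). From day 4 to day 14 it was 1 by upper quartile, 4 by DESeq2, 30 by voom, 1 without the 3 libraries apart, 1 without rats 139 and 140 and 234 with 2 surrogate variables. By library size it was 279 (4 higher, 275 lower, median -0.311).

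With each library left out in turn, genes called ranged 0 to 2 at 6 hours, 0 to 0 at day 4, 0 to 0 at day 14, 0 to 1 in the joint test, 0 to 1 for day 4 against 6 hours and 0 to 0 for day 14 against day 4. Time changes ranged 976 to 2793 and 0 to 918 in controls, and 665 to 2189 and 0 to 4 in treated rats. Lists ranged 18 to 24 at 6 hours, 4 to 19 at day 4 and 3 to 8 at day 14. Called values that changed sign, or values that did so beyond their standard errors, were 4: Acta2 at 6 hours with 2 surrogate variables (0.26), Dnaja1 (0.00826, library size only) and Rgs5 (-0.0216, 2 surrogate variables) in controls from 6 hours to day 4, and Mmp9 (-4.24, high series) from day 4 to day 14. Without rats 139 and 140 the signs of Cd68 (0.41), Mrc1 (0.35), Acta1 (-0.01), Acta2 (0.26) and Myh3 (1.31), among other panel genes, also changed at 6 hours.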

Other observations

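The comparison of the 2 rat-number series, the omission of rats 139 and 140, the tests of Mif by rat and by library, the tests of clock genes and the groupings for lists that differed between times or by balance of the series were chosen only after the result was seen. Of 100 groupings of the same rats, only the real one reached the 2160 genes of controls between 6 hours and day 4 (highest other 2087). The same held for the 1521 genes of treated rats (1 of 100, highest other 1232). At unadjusted p under 0.05 by edgeR, another grouping of treated rats held 4100 genes, against 4063 in the real one. All 100 groupings were at least as balanced by series as the real one, in controls and in treated rats. Chance is thus unlikely over all groupings, but was not judged among groupings as unbalanced as the real ones. For the 104 genes of controls from day 4 to day 14, 7 of 100 groupings gave as many (highest other 1725), so chance is not excluded over all groupings. Among the 79 with the series no less balanced than in the real one, 3 gave as many (highest other 1725), and 4 of the other 21 did. The verdict on chance thus depends on which groupings are compared. For treated rats the real count was 0, which any grouping matches (100 of 100, highest other 24), so nothing follows from it. In controls a grouping with 1725 calls may point to a structure of the samples other than time, but its make-up was not examined. Without control rat 193 of day 4 the real grouping itself gave 918 genes. Time goes together with the rat-number series and the number of operations: with a series term 593 genes passed in controls and 214 in treated rats between 6 hours and day 4. The 17 lists of controls over that interval were matched in 24 of 100 groupings (highest other 24) and the 19 of day 14 against day 4 in 9 (highest other 22). For treated rats the 14 lists were matched in 44 of 100 (highest other 22) and the 13 in 45 (highest other 22), so chance is not excluded for numbers of lists over time.

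For plasma against control, 30 of 100 groupings gave at least the 1 gene of 6 hours (highest other 553). At unadjusted p under 0.05 by edgeR, 17 of 100 held at least the 1172 genes of 6 hours (highest other 4604). For the 177 genes of day 4 it was 73 (highest other 2342), and for the 328 of day 14 it was 91 (highest other 4047). Counts of 0 are matched by any grouping and decide nothing: 100 of 100 for day 4 (highest other 3) and for day 14 (highest other 1410), for the joint test (highest other 6), and for the differences of day 4 against 6 hours (highest other 1) and of day 14 against day 4 (highest other 1232). Groupings with 553 and 1410 calls may point to a structure of the samples. At 6 hours groupings that parted rats 139 and 140 called at most 1 gene. Of the 42 others that kept them together, 13 called any gene, up to 553. Keeping these rats together was thus not enough for calls, and the place of other rats was not examined. At day 14 the groupings that set the rat-number series against each other held the highest count, and the others at most 27. Lists whose plasma effect differed were matched in 32 of 100 between day 4 and 6 hours (real count 15, highest other 25) and in 55 between day 14 and day 4 (10 and 23). Lists at day 4 were matched in 52 of 100 (real count 12, highest other 25) and at day 14 in 70 (6 and 19). Correlations between times were matched in 29 of 100 for 6 hours with day 4 (0.125, highest other 0.312), 69 for 6 hours with day 14 (-0.0577 and -0.367) and 73 for day 4 with day 14 (-0.0483 and 0.273). Chance is not excluded for the gene at 6 hours, these unadjusted counts, these lists or the correlations.

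No other grouping reached the 23 lists at 6 hours (1 of 100), but the highest other held 22. With single libraries left out the real count ran from 18 to 24, so chance is not firmly excluded for the number. Nerve tissue in the samples of rats 139 and 140 could give part of it, as 15 lists were called without them, 13 of the 23 and 2 others, and chance could give as many in 22 of 100 groupings (highest other 20). The lower depth of rat 139 does not account for it, since 21 lists shifted with every library thinned to its total. Rats 139 and 140 also hold the highest mitochondrial shares (38.3% and 36.9%) and the lowest depths at 6 hours, so nerve content and sample quality cannot be told apart. A response to plasma is undecided: 13 lists shifted in the same direction with and without the 2 rats, and the medians of cytokine (-1.30 and -1.14), immediate early (-0.66 and -0.61), NF-kB (-0.30 and -0.25) and NRF2 genes (-0.29 and -0.28) hardly moved, so these 2 rats do not account for those 4 lists.

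The call of Mif rests on 3 rats, and treatment may or may not be the cause. A lowering by plasma is undecided: of 6 untreated rats at 6 hours, 3 lay above the range of the treated rats, 2 within it and 1 below it. A difference of the whole library is unlikely, as 0 other genes separated the same 3 rats from the other 33 by 3-fold. Reads shared with near-identical copies remain undecided, as on-off genes had listed copies about as often as others (Fisher's exact p = 0.579). Sequencing of the gene in these rats would decide.

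The 2 rat-number series differed in 4292 genes at equal treatment and time (1 of 100 groupings, highest other 4), so chance is excluded. Clock genes were among them: Arntl was lower in the low series (log2 fold change -1.74, SE 0.22), while Dbp (2.45) and Per3 (1.31) were higher. Tissue collected at another hour of the day could give this pattern of clock genes. Of the 11 called, Bhlhe41 was given no phase, and 0 of the others moved against the phase of the rest. The clock list was not called by camera (adjusted p = 0.129) but was by fry (adjusted p = 0.00759). Camera called 4 other lists. Macrophage (adjusted p = 0.000308), collagen (0.000944) and TGF-beta genes (0.00141) were higher in the low series, oxidative phosphorylation genes (0.000101) lower. With an estimated correlation 0 lists were called. The cause of these list differences was not tested. Sequencing depth does not account for the 4292 genes, since 3606 genes differed with every library thinned to the lowest total. A record of the hour of collection would decide for the clock genes only.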
